A study of Mus musculus with 12 samples.

How the data were processed

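The series holds 12 mRNA libraries of primary neurons from C57BL/6 mice, collected on day 10 of 2 treatments. Libraries were made after enrichment of mRNA with oligo-dT beads, per the labels' protocols. In the oncogene model, over-expression of H-Ras(G12V), a constitutively active form of the small GTPase H-Ras, by an adeno-associated virus was set against mCherry, a fluorescent protein. In the chemical model, etoposide, a topoisomerase II poison that causes DNA breaks, was set against its solvent DMSO. Each of the 4 groups has 3 libraries. The labels do not say whether the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

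The labels of the etoposide and DMSO libraries contradict each other. For these 6 libraries the treatment tag gives the opposite group to the title and the library name, and the column names of the deposited table follow the title. Groups were taken from the titles before the data were examined. Every direction given for etoposide holds for the libraries titled etoposide.

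The deposited tables, 1 per model, give FPKM (fragment counts corrected for transcript length and for the library total) per gene and library with 2 decimals, per the file headers. The submitters' processing notes name HISAT, Bowtie2, RSEM and the mouse genome build mm9, with no version or role for the tools. Any filter or scaling beyond FPKM is not given in the sources used here. The 2 tables list 18223 and 17800 genes, 17416 of them in both, and were treated as normalised separately, so each effect was tested within its own table. Read counts were not used here, and no count model was fitted. Genes are named by the symbols of the tables, no coordinates are printed, and mitochondrially encoded genes were not analysed here.

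The tables give no depth. A rough estimate was made from the steps of low FPKM values in genes with a single annotated transcript, with transcript lengths of GENCODE release M21, which belongs to another build than mm9. It gave 15600000 to 17700000 fragments for the H-Ras(G12V) and mCherry libraries and 25400000 to 31800000 for the etoposide and DMSO libraries. For etoposide library 3 the estimate was unstable, at 28700000 fragments over all genes used and 58600000 and 28800000 when these genes were parted in 2 sets. With counts rebuilt from these depths, chi-square per degree of freedom between libraries of a group was 3.23 for mCherry libraries 1 and 2 and between 13.6 and 534 for the other pairs. All pairs differed by more than sampling noise by this approximate measure, and all 12 libraries were kept.

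Values were analysed as log2(FPKM + 1) in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with trend), for genes with a mean of at least 1 FPKM over the 6 libraries of a table. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale and understate the change of genes at low levels. Folds given as ratios are ratios of group means of FPKM. The 2 models share no control libraries. Their effects were compared through the genes called in both, through the correlation of log2 fold changes across genes, and through an interaction contrast over the 12 libraries, which is the H-Ras(G12V) effect minus the etoposide effect. P-values of the interaction contrast rest on a spread pooled over the 4 groups.

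27 gene lists were fixed before the data were examined. They covered complement, p53 targets, cell-cycle inhibitors with senescence-associated nuclear and lysosomal genes, secreted factors of senescence, RAS-ERK output, immediate early genes, the type I interferon response and MHC class I presentation. They also covered NF-kappaB targets, DNA replication and mitosis, the integrated stress response, NRF2 targets, lysosome and autophagy, cholesterol biosynthesis, oxidative phosphorylation, presynaptic and postsynaptic genes, mitochondrially encoded mRNAs, and markers of neurons and of the other cell types such a culture can hold. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run beside it.

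Named genes followed a rule fixed before the data were examined. It took 12 fixed genes, up to 6 genes per direction with the largest log2 fold change among called genes whose groups did not overlap and whose higher group averaged at least 5 FPKM, and up to 4 called members of each passing list or 2 of each other list. It also took up to 5 genes per direction called in opposite directions in the 2 models with a passing interaction. The text gives a part of the list members, taken from the top of this ranking, and some genes that the rule took are not reported here. They stay in the counts.

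Before the data were examined, the alternatives chosen were other pseudocounts (0.1 and 5), other filters (no filter, or a mean of at least 5 FPKM), scaling to a common sum or by median of ratios, a replicate block, robust eBayes, a single fit of all 12 libraries, and leaving out each library in turn. Averaging mCherry libraries 1 and 2 and leaving out the third mCherry and etoposide libraries together were added after seeing the data. The rank of the real grouping among all 10 splits of each table's 6 libraries, and among the 100 pairs of splits, was counted. The depth test of etoposide library 3 replaced an earlier one on estimated fragments, and its cutoff of 20 FPKM was set after cutoffs of 50 and 100 FPKM had also been looked at. The share of genes apart in that library was 11.2%, 9.87% and 12.9% in turn, against at most 2.33%, 1.24% and 0.266% in a DMSO library.

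The fits were tested on simulated data drawn from each gene's mean and spread, with 200 changed genes per comparison and 199 for the interaction. Genes were drawn independently, so no library stood apart as a whole, and changed genes were taken only from those above a minimum level. For the interaction, only the H-Ras(G12V) data held changed genes. The shares called below may therefore not carry over to the real libraries or to low genes. In the H-Ras(G12V) comparison, with 12724 genes, 52% of genes changed 2-fold and 94% of those changed 4-fold were called. In the etoposide comparison, with 12371 genes, 1% of genes changed 2-fold and 52% of those changed 4-fold were called. For the interaction, with 12179 genes, 8% of genes changed 2-fold and 74.7% of those changed 4-fold were called. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.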

Results

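Gene expression was measured as FPKM in primary mouse neurons 10 days into 2 treatments that the study uses as models of neuronal ageing. These are oncogene-induced senescence by H-Ras(G12V), with 3 libraries against 3 mCherry controls, and stress-induced senescence by etoposide, with 3 libraries against 3 DMSO controls. The series asks which pathways the models share, and its title concerns complement C4. The libraries held between 11829 and 12728 genes at 1 FPKM or more. Roughly estimated depth was 15600000 to 17700000 fragments per H-Ras(G12V) or mCherry library and 25400000 to 31800000 per etoposide or DMSO library.

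Libraries of some groups stood apart from the others of their group. Across genes, mCherry library 3 had rank correlations of 0.929 and 0.925 with mCherry libraries 1 and 2, which correlated at 0.997 with each other, and of 0.928 to 0.940 with the H-Ras(G12V) libraries. Across the 2 tables, over genes listed in both, it had rank correlations of 0.960, 0.955 and 0.910 with DMSO libraries 1, 2 and 3. In the same order these were 0.941, 0.944 and 0.885 for mCherry library 1 and 0.939, 0.942 and 0.878 for mCherry library 2. Etoposide library 3 had rank correlations of 0.811 and 0.881 with etoposide libraries 1 and 2, and of 0.931 to 0.979 with the DMSO libraries. DMSO library 3 had rank correlations of 0.956 and 0.943 with DMSO libraries 1 and 2, which correlated at 0.986, and lay at 46.6 on the second principal component against -7.41 and -15.6. Genes are not independent replicates, and these values describe the libraries only.

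The first comparison asked what H-Ras(G12V) over-expression changes. The cell-cycle inhibitors Cdkn2a and Cdkn2b rose from 2.05 ± 1.56 to 33.2 ± 14.5 FPKM and from 3.72 ± 1.52 to 26.9 ± 4.06 FPKM (SD, n = 3 per group), with limma adjusted p of 0.00481 and 0.00233. Cdkn1a, which encodes the inhibitor p21, rose from 48.7 ± 22.0 to 169 ± 33.9 FPKM (adjusted p = 0.0115), and Trp53, which encodes p53, rose from 25.2 ± 2.15 to 39.4 ± 2.24 FPKM (adjusted p = 0.0159). Of 45 DNA replication and mitosis genes 33 rose, and of 38 RAS-ERK genes 18 rose (adjusted p = 0.291 for each list with an estimated correlation). Of 42 postsynaptic genes 15 fell, and of 19 fibroblast, meningeal and mural markers 13 fell (adjusted p = 0.225 for each list with an estimated correlation). In all, 2161 of 12724 tested genes passed, 1312 higher and 849 lower, of which 500 and 282 differed by at least 1 log2 unit. The groups did not overlap for 40.3% of tested genes, where chance gives 10%.

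The split of these calls depended on the scaling of the libraries. The share of higher calls was 60.7% on FPKM as deposited, 39.2% (863 higher and 1339 lower) after scaling to a common sum and 49.3% (1051 higher and 1083 lower) with median-of-ratios scaling. The median log2 difference over all genes was 0.05, -0.08 and -0.01 in turn. Without mCherry library 3 the count was 5722, and without any other single library of this table it was between 507 and 1158. The first of these fits keeps only mCherry libraries 1 and 2 as controls, which correlated at 0.997, so its p-values rest on a small spread. With these 2 libraries averaged into 1, the count was 630. Cdkn2a and Cdkn2b passed without each library in turn. Cdkn1a did not pass without H-Ras(G12V) library 2 or 3 (adjusted p = 0.0534 and 0.0513), nor Trp53 without H-Ras(G12V) library 1 or 3 (0.0615 and 0.0659) or mCherry library 1 or 2 (0.0526 and 0.0710), with mCherry libraries 1 and 2 averaged (0.0606) or in a single fit of the 12 libraries (0.441). The single fit takes its spread from all 4 groups, and Trp53 read 59.8, 59.2 and 15.4 FPKM in etoposide libraries 1, 2 and 3. That fit's p-value therefore does not measure the H-Ras(G12V) and mCherry spread alone, and the log2 fold change was unchanged at 0.628.

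Mouse Hras itself averaged 41.2 ± 9.39 FPKM in the libraries labelled H-Ras(G12V) and 44.4 ± 1.49 in the mCherry libraries (log2 fold change -0.13, adjusted p = 0.624). The labels do not give the species or sequence of the transgene, so this gene may not read it and does not check the labels. C4b, which encodes complement component C4, averaged 19.1 ± 1.09 FPKM in the libraries labelled H-Ras(G12V) and 8.80 ± 5.98 in the controls. Its log2 fold change of 1.20 ± 0.37 (SE) did not pass (adjusted p = 0.0655). The control libraries read 5.55, 5.16 and 15.7 FPKM. Without mCherry library 3 the log2 fold change was 1.66 (adjusted p = 5.43e-05), and adjusted p ranged from 5.43e-05 to 0.181 over 16 alternatives. The lowest value rests on the close pair of mCherry libraries 1 and 2 as the only controls. C4b and C4a are near-identical copies, so reads can be split between them. C3, the central component of the complement cascade, averaged 4.34 ± 3.09 against 0.390 ± 0.473 FPKM (adjusted p = 0.0484). It did not pass without H-Ras(G12V) library 1 or 2 (adjusted p = 0.147 and 0.130) or mCherry library 1 or 2 (0.130 and 0.0713). Nor did it pass with a pseudocount of 5 (0.0695), no filter (0.0710), median-of-ratios scaling (0.0536) or mCherry libraries 1 and 2 averaged (0.0966). Of 16 tested complement genes 2 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.180). That list passed upward without H-Ras(G12V) library 3 (camera adjusted p = 0.0360) and with a mean of at least 5 FPKM (0.0377, 5 tested).

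Mdm2, a p53 target that encodes the ubiquitin ligase of p53, read 32.2 ± 4.42 against 21.1 ± 3.49 FPKM (adjusted p = 0.0499), and of the alternatives run it passed only without mCherry library 3 (adjusted p = 0.00465). Lmnb1, which encodes lamin B1, read 56.5 ± 5.82 against 30.3 ± 10.6 FPKM (adjusted p = 0.0536). Glb1, which encodes lysosomal beta-galactosidase, read 23.1 ± 1.90 against 16.8 ± 2.70 FPKM (adjusted p = 0.0765). The stress-induced cytokine Gdf15 read 6.14 ± 3.33 against 2.62 ± 2.54 FPKM (adjusted p = 0.170). Without mCherry library 3, Lmnb1, Glb1 and Gdf15 passed with adjusted p of 0.00452, 0.00502 and 0.00517. These p-values, and that of Mdm2 without this library, rest on the close pair of mCherry libraries 1 and 2 as the only controls. Il6 averaged under 1 FPKM over the 6 libraries and was not tested.

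The largest rises were in genes near 0 in the controls. Gal, which encodes the neuropeptide galanin, rose from 0.467 ± 0.394 to 219 ± 99.8 FPKM, and Sprr1a, known from injured neurons, rose from 0.210 ± 0.0693 to 95.2 ± 52.0 FPKM. Hmga1b read 56.9 ± 20.8 against 0.0667 ± 0.0611 FPKM and shares sequence with Hmga1, so its level is uncertain. Gimap6 rose from 0.413 ± 0.640 to 45.2 ± 9.14 FPKM and Crisp1 from 0.173 ± 0.258 to 30.7 ± 10.3 FPKM. Lce1g was listed at 0 in each mCherry library and at 27.6, 55.9 and 15.5 FPKM in the libraries labelled H-Ras(G12V). Among the largest falls, Igf2, a growth factor, fell from 131 ± 31.2 to 2.97 ± 1.46 FPKM, Col3a1 from 34.7 ± 10.5 to 1.61 ± 0.290, Postn from 25.9 ± 14.7 to 0.963 ± 0.0896 and Vtn from 15.6 ± 7.67 to 0.513 ± 0.202. Limma adjusted p lay at 0.00567 or below for these genes.

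**Figure D1:**
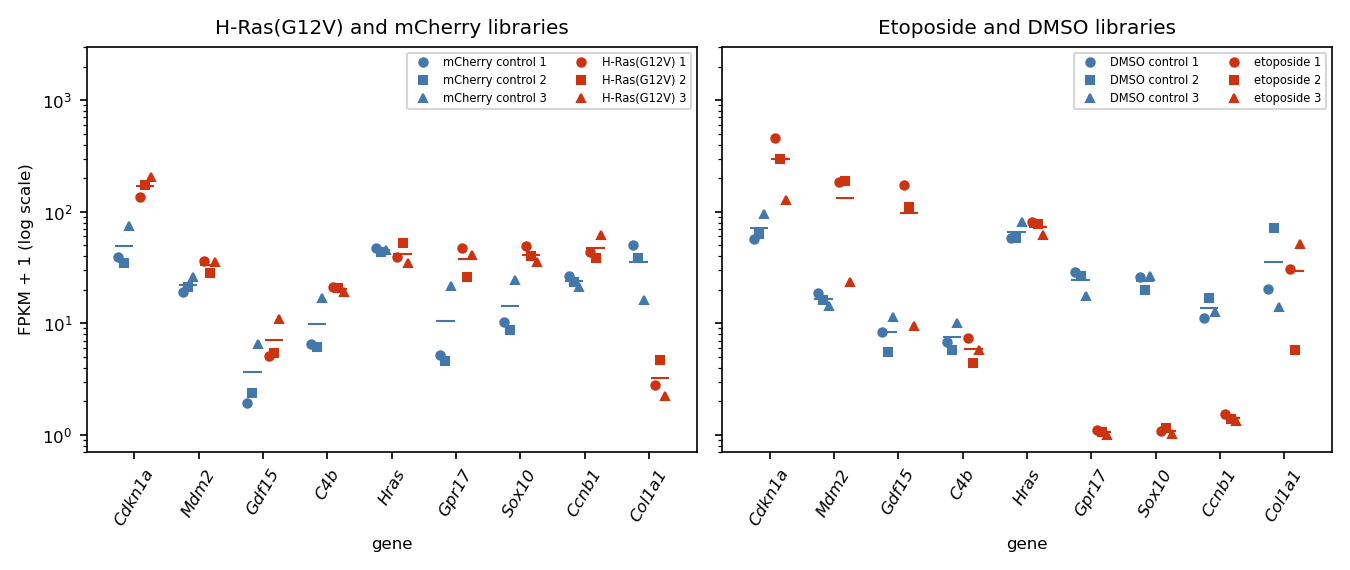
FPKM + 1 (log axis) of 9 genes in each library, with H-Ras(G12V) and mCherry libraries on the left and etoposide and DMSO libraries on the right; symbols are single libraries and lines are group means. C4b reads 5.55, 5.16 and 15.7 FPKM in the mCherry libraries, and Mdm2 reads 182, 189 and 22.2 FPKM in the etoposide libraries.

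Lists of senescence-associated and stress genes moved up with H-Ras(G12V). The DNA replication and mitosis list moved up as well, so these rises do not show that cells stopped dividing. Of 36 tested p53 targets 17 rose and 0 fell, 19 when adjusted over the list alone (camera adjusted p = 2.26e-05; adjusted p = 0.225 with an estimated correlation), among them Gadd45a (15.2 ± 1.58 against 5.44 ± 2.89 FPKM) and Fas (10.3 ± 0.964 against 3.63 ± 1.95 FPKM). Of 18 cell-cycle inhibitors and senescence-associated genes 6 rose, 10 when adjusted over the list alone (camera adjusted p = 0.00104; adjusted p = 0.225 with an estimated correlation). The list's members include Hmgb2, which rose from 27.4 ± 8.39 to 71.2 ± 13.7 FPKM and is a chromatin protein that usually goes with proliferation. Of 44 secreted factors 16 rose and 2 fell, 22 and 3 when adjusted over the list alone (camera adjusted p = 2.26e-05; adjusted p = 0.225 with an estimated correlation), with the protease inhibitors Serpinb2 at 19.7 ± 7.51 against 0.153 ± 0.112 FPKM and Timp1 at 63.0 ± 27.6 against 5.28 ± 3.31 FPKM. Of 34 genes of the integrated stress and unfolded protein response 14 rose, 21 when adjusted over the list alone (camera adjusted p = 9.56e-06; adjusted p = 0.225 with an estimated correlation), including Atf3 (7.09 ± 1.56 against 2.63 ± 1.79 FPKM).

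Of 38 RAS-ERK output and feedback genes 18 rose and 1 fell, 24 and 1 when adjusted over the list alone (camera adjusted p = 1.50e-08; adjusted p = 0.291 with an estimated correlation). The chromatin factor Hmga2 rose from 0.187 ± 0.0643 to 13.6 ± 4.32 FPKM, the ligand Areg from 0.373 ± 0.196 to 7.77 ± 1.25 and the ERK phosphatase Dusp5 from 2.19 ± 1.72 to 16.3 ± 4.12. Of 22 immediate early genes 5 rose and 2 fell, 6 and 3 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0619). It passed upward under both scalings (camera adjusted p = 0.00945 and 0.0285), without mCherry library 3 (4.00e-06) and without H-Ras(G12V) library 1 (0.0466). In mCherry library 3 Egr1 read 26.7 FPKM, against 2.86 and 3.75 in mCherry libraries 1 and 2 and 39.7 to 55.5 in the libraries labelled H-Ras(G12V). The median of the whole list, relative to the mCherry mean, lay at 1.38 in mCherry library 3 and at -0.48 and -0.66 in mCherry libraries 1 and 2. It was lower than in mCherry library 3 in each library labelled H-Ras(G12V), at 0.76, 1.17 and 0.95.

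Of 45 DNA replication and mitosis genes 33 rose and 0 fell, 42 when adjusted over the list alone (camera adjusted p = 5.61e-14; adjusted p = 0.291 with an estimated correlation). Mcm5, a subunit of the replicative helicase, rose from 9.45 ± 1.08 to 22.5 ± 3.79 FPKM. Of 32 lysosome and autophagy genes 11 rose and 1 fell, 17 and 1 when adjusted over the list alone (camera adjusted p = 0.000243; adjusted p = 0.413 with an estimated correlation), including the cathepsin gene Ctsd (565 ± 148 against 263 ± 66.6 FPKM). Of 16 MHC class I genes 5 rose, 8 when adjusted over the list alone (camera adjusted p = 0.00848; adjusted p = 0.291 with an estimated correlation). Of 18 NF-kappaB targets 3 rose, 3 when adjusted over the list alone (camera adjusted p = 0.00903; adjusted p = 0.397 with an estimated correlation), with Lcn2 at 54.4, 102 and 16.2 FPKM against 1.63, 4.80 and 6.73. That list call was lost without H-Ras(G12V) library 2 (camera adjusted p = 0.0509).

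Of 20 NRF2 targets 3 rose, 1 when adjusted over the list alone (camera adjusted p = 0.0409; adjusted p = 0.291 with an estimated correlation). Of 49 oxidative phosphorylation subunits 0 passed singly, 0 when adjusted over the list alone, and the list passed upward (camera adjusted p = 0.0200; adjusted p = 0.654 with an estimated correlation). Both of these list calls were lost when libraries were scaled to a common sum (camera adjusted p = 0.0810 and 0.154) or by median of ratios (0.0586 and 0.0671). Without H-Ras(G12V) library 3 they were at 0.0513 each, without mCherry library 1 at 0.0770 and 0.0764, and without mCherry library 2 at 0.108 and 0.198. With mCherry libraries 1 and 2 averaged they were at 0.0926 and 0.127. The NRF2 call was also lost without H-Ras(G12V) library 2 (0.0532) and with no filter (0.0567). The type I interferon list, with 1 of 23 genes higher and 2 lower, did not pass (camera adjusted p = 0.0992), and the counts adjusted over the list alone were 1 and 1. It passed downward with no filter (camera adjusted p = 0.00176, 47 tested) and without mCherry library 1 (0.0399). Cholesterol biosynthesis, with 1 of 23 higher and 0 when adjusted over the list alone, did not pass either (camera adjusted p = 0.411), and its mean changed sign when libraries were scaled to a common sum.

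Neuronal lists moved down. Of 42 postsynaptic genes 15 fell and 0 rose, 17 when adjusted over the list alone (camera adjusted p = 4.30e-09; adjusted p = 0.225 with an estimated correlation), including Gria1, a glutamate receptor subunit (39.2 ± 0.678 against 105 ± 32.4 FPKM), and Gabra5, a GABA receptor subunit (35.4 ± 3.90 against 110 ± 12.2 FPKM). Of 35 presynaptic genes 8 fell and 0 rose, 11 when adjusted over the list alone (camera adjusted p = 2.26e-05; adjusted p = 0.341 with an estimated correlation), including Cplx2 (63.9 ± 2.88 against 150 ± 24.1 FPKM). Of 15 excitatory neuron markers 8 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.000808; adjusted p = 0.225 with an estimated correlation). Of 16 inhibitory neuron markers 6 fell and 2 rose, 7 and 2 when adjusted over the list alone (camera adjusted p = 0.00183; adjusted p = 0.291 with an estimated correlation). That call was lost without mCherry library 3 (camera adjusted p = 0.127). Of 18 pan-neuronal markers 4 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.0402; adjusted p = 0.225 with an estimated correlation). That call was lost under both scalings (camera adjusted p = 0.141 and 0.0760) and without H-Ras(G12V) library 3 (0.0704).

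Markers of other cell types moved with the groups. A change in the mixture of cells therefore cannot be told apart here from a change within neurons, also for the neuronal lists. Of 11 oligodendrocyte lineage markers 8 rose, 11 when adjusted over the list alone (camera adjusted p = 2.26e-05; adjusted p = 0.341 with an estimated correlation), with the transcription factor Olig2 at 206 ± 31.2 against 62.2 ± 34.2 FPKM. Of 20 astrocyte markers 4 rose, 6 when adjusted over the list alone (camera adjusted p = 0.000866; adjusted p = 0.393 with an estimated correlation), with Aldh1l1 at 142 ± 16.8 against 48.0 ± 2.73 FPKM. Of 13 neural progenitor markers 4 rose, 5 when adjusted over the list alone (camera adjusted p = 0.00149; adjusted p = 0.225 with an estimated correlation), with the intermediate filament genes Nes at 90.5 ± 9.48 against 28.7 ± 0.863 FPKM and Vim at 1528 ± 268 against 533 ± 67.3 FPKM. Of 19 fibroblast, meningeal and mural markers 13 fell and 1 rose, 14 and 1 when adjusted over the list alone (camera adjusted p = 4.50e-10; adjusted p = 0.225 with an estimated correlation). Cspg4, which is also on the oligodendrocyte list, was the member that rose. Microglial markers, with 1 of 11 higher, Cd68, and 1 when adjusted over the list alone, did not pass (camera adjusted p = 0.132). They passed upward with scaling to a common sum (camera adjusted p = 0.0277), without H-Ras(G12V) library 3 (0.00883), without mCherry library 1 or 2 (0.0352 and 0.0114) and with these 2 libraries averaged (0.0220). In mCherry library 3 the list medians lay at 0.85 for oligodendrocyte, 0.69 for astrocyte and -1.45 for microglial markers, relative to the mCherry mean. Endothelial markers, with 0 of 3 called and 1 lower when adjusted over the list alone, did not pass (camera adjusted p = 0.754), and their median and mean differed in sign. In total 14 lists passed upward and 6 downward of 26, 16 passed by fry, and 0 passed with an estimated correlation. Other splits of these 6 libraries, each with 0 genes called, still gave 9 to 15 passing lists by camera at the preset correlation. A camera pass alone therefore does not show an effect of the groups.

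**Figure D2:**
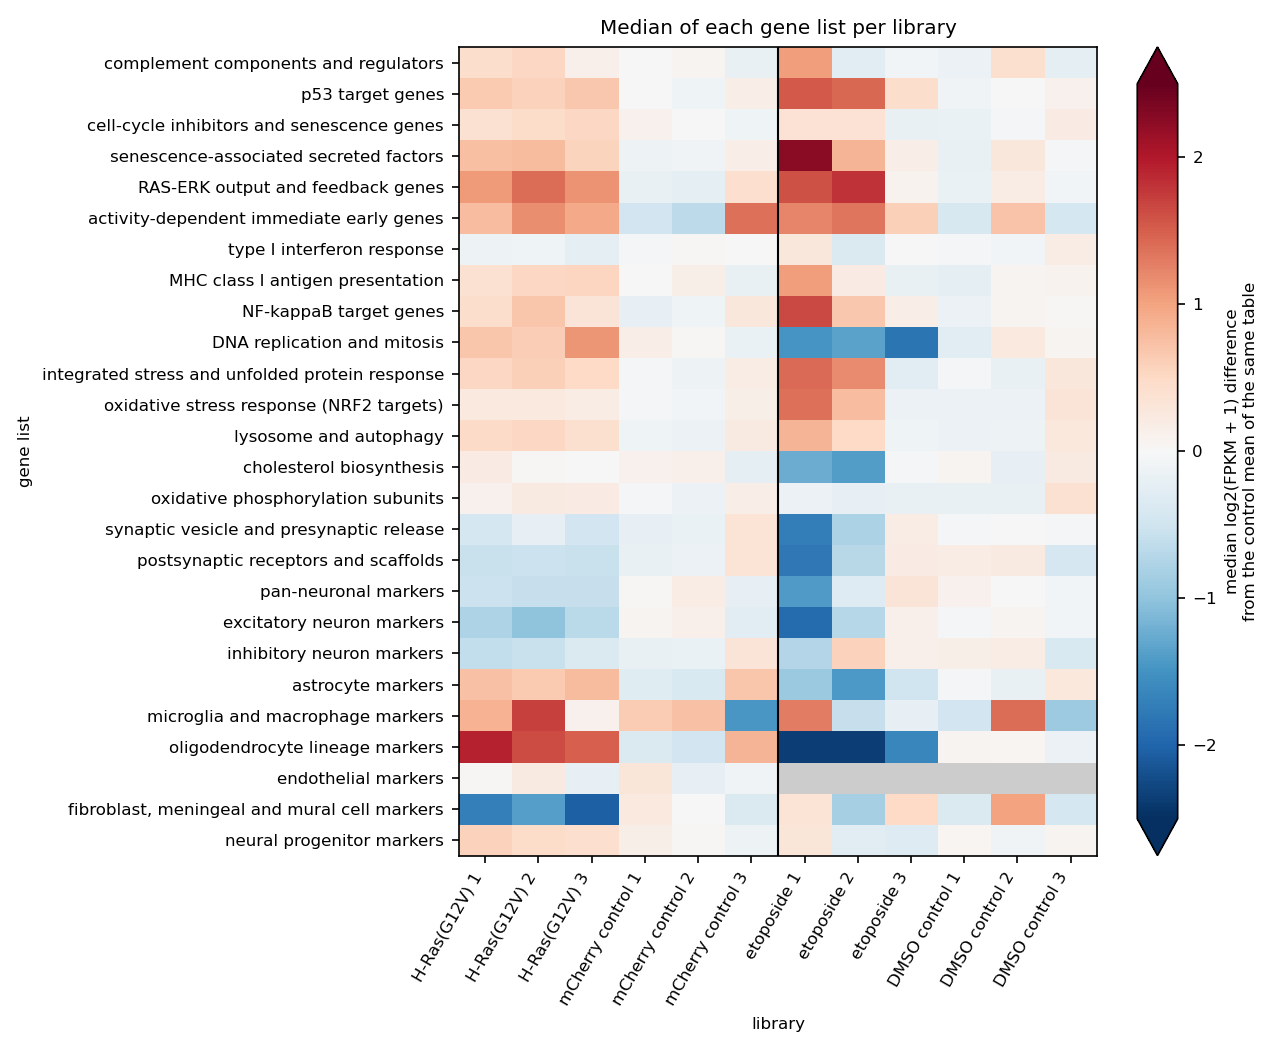
Median over each gene list's members of the log2(FPKM + 1) difference from the control mean of the same table (colour, log2 units), with lists in rows and the 12 libraries in columns; grey marks a list that was not tested. The DNA replication and mitosis list is at -1.47, -1.34 and -1.82 in etoposide libraries 1, 2 and 3, and the p53 target list at 1.54, 1.44 and 0.44.

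The second comparison asked what etoposide changes. Of 10 oligodendrocyte lineage markers 4 fell, and of 40 DNA replication and mitosis genes 14 fell (adjusted p = 0.0278 and 0.259 with an estimated correlation). Gpr17, a receptor of the oligodendrocyte lineage, fell from 23.3 ± 5.96 to 0.0533 ± 0.0551 FPKM, and Sox10, a transcription factor of that lineage, from 23.1 ± 3.70 to 0.0800 ± 0.0656 FPKM (SD, n = 3 per group; limma adjusted p = 0.000497 for each). Ube2c and Ccnb1, which act in mitosis, fell from 25.4 ± 6.61 to 0.977 ± 0.290 and from 12.6 ± 3.03 to 0.420 ± 0.108 FPKM (adjusted p = 0.00195 and 0.00226). Pdgfra, the receptor that marks oligodendrocyte precursors, fell from 51.0 ± 15.8 to 3.30 ± 1.54 FPKM, Bcas1 from 11.4 ± 4.82 to 0.0533 ± 0.0379 and Rlbp1 from 26.9 ± 8.13 to 1.60 ± 0.580. Without DMSO library 3, Ube2c and Ccnb1 were at an adjusted p of 0.0587 and Pdgfra and Rlbp1 at 0.0592. Without etoposide library 2, Pdgfra and Rlbp1 were at 0.0508 and 0.0514, and Bcas1 did not pass either. Gpr17 and Sox10 passed without each library in turn. Markers of other cell types moved here too, so a change in the mixture of cells cannot be told apart from a change within neurons.

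In limma 56 of 12371 tested genes passed, 56 lower and 0 higher. At an unadjusted p under 0.05 there were 918 higher and 806 lower genes. Groups did not overlap for 15.8% of genes, where chance gives 10%. Without etoposide library 3 the count was 3908, with 2259 higher and 1649 lower, and the 56 genes were among them. It was 6 without etoposide library 2, 22, 28 and 4 without DMSO libraries 1, 2 and 3, and 41 without etoposide library 1.

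Of the p53 targets and other fixed genes, several read higher in etoposide libraries 1 and 2 than in library 3. Mdm2 read 182, 189 and 22.2 FPKM in etoposide libraries 1, 2 and 3 against 15.3 ± 2.26 in DMSO (adjusted p = 0.300), and Gdf15 read 174, 109 and 8.49 FPKM against 7.40 ± 2.90 (adjusted p = 0.353). Cdkn1a read 461, 295 and 126 FPKM against 70.4 ± 20.2 (adjusted p = 0.210), and Cdkn2b 19.7, 15.3 and 5.71 FPKM against 3.18 ± 0.384 (adjusted p = 0.241). Without etoposide library 3 these 4 genes passed, with log2 fold changes of 3.52, 4.10, 2.41 and 2.14. Trp53 (44.8 ± 25.5 against 21.2 ± 4.90 FPKM, adjusted p = 0.415), Il6 (3.73 ± 3.83 against 0.0267 ± 0.0462 FPKM, adjusted p = 0.353) and Lmnb1 (8.57 ± 2.91 against 23.4 ± 3.25 FPKM, adjusted p = 0.168) also passed without that library. Among the other alternatives, Lmnb1 and Cdkn2b passed in a single fit of the 12 libraries (adjusted p = 0.0385 and 0.0464), and the others of these 7 genes passed in none. The single fit pools the spread of all 4 groups. C4b read 4.86 ± 1.49 against 6.55 ± 2.29 FPKM (adjusted p = 0.568), Hras 72.7 ± 9.82 against 64.5 ± 12.6 (adjusted p = 0.725), Cdkn2a 4.83 ± 0.968 against 4.16 ± 2.47 (adjusted p = 0.710) and Glb1 21.3 ± 5.54 against 19.6 ± 3.72 (adjusted p = 0.861). C3 averaged under 1 FPKM and was not tested.

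Of 40 DNA replication and mitosis genes 14 fell and 0 rose, 31 when adjusted over the list alone (camera adjusted p = 1.21e-31; adjusted p = 0.259 with an estimated correlation). Of 10 oligodendrocyte lineage markers 4 fell and 0 rose, 9 when adjusted over the list alone (camera adjusted p = 1.39e-14), and this was the list that also passed with an estimated correlation (adjusted p = 0.0278). That pass was lost with no filter (0.140) or scaling to a common sum (0.0891), without etoposide library 2 or 3 (0.0769 and 0.221) and without DMSO library 1, 2 or 3 (0.0856, 0.110 and 0.145). These 2 lists were also those that passed by fry. Among 13 neural progenitor markers 2 fell, among them Hes5, with 2 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.130), except without etoposide library 1 (0.00137). Hes5 was at an adjusted p of 0.147 without etoposide library 2, 0.159 without DMSO library 3, 0.0786 without DMSO library 1 and 0.0757 with no filter.

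The remaining lists had 0 members called over all genes. Upward calls were made for p53 targets (36 tested, 23 higher when adjusted over the list alone, camera adjusted p = 2.42e-14), secreted factors (45 tested, 13 higher and 1 lower, 1.58e-05), RAS-ERK genes (38 tested, 11 higher, 2.14e-05), immediate early genes (22 tested, 10 higher, 0.000192) and NF-kappaB targets (21 tested, 3 higher, 0.00240). With an estimated correlation, adjusted p was 0.529 for p53 targets and 0.655 for secreted factors, RAS-ERK genes, immediate early genes and NF-kappaB targets. Upward calls were also made for the integrated stress response (34 tested, camera adjusted p = 1.85e-05), NRF2 targets (22 tested, 0.00260) and lysosome and autophagy (32 tested, 0.00830), each with 0 when adjusted over the list alone. With an estimated correlation, adjusted p was 0.655, 0.665 and 0.703 in turn. Downward calls were made for astrocyte markers (19 tested, 7 lower when adjusted over the list alone, camera adjusted p = 4.86e-06; adjusted p = 0.529 with an estimated correlation). With 0 when adjusted over the list alone, they were also made for cholesterol biosynthesis (23 tested, camera adjusted p = 8.90e-09), presynaptic genes (35 tested, 2.01e-07), postsynaptic genes (42 tested, 1.11e-07), excitatory markers (14 tested, 0.000329), pan-neuronal markers (18 tested, 0.000751) and oxidative phosphorylation (49 tested, 0.00330). With an estimated correlation, adjusted p was 0.719 for oxidative phosphorylation and 0.655 for the other 5 of these lists.

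In etoposide library 3 several of these lists lay near the DMSO libraries. Its median differences from the DMSO mean were 0.09 for RAS-ERK genes and 0.13 for excitatory markers, against 1.60 and -1.93 in library 1 and 1.81 and -0.72 in library 2. Without that library 27 p53 targets rose and 1 fell, 23 integrated stress genes and 13 NRF2 targets rose, and 16 cholesterol genes, 24 presynaptic and 24 postsynaptic genes fell. 6 lists with 0 called members, over all genes and when adjusted over the list alone unless given, did not pass. These were complement (12 tested, camera adjusted p = 0.432), interferon (18 tested, 0.619), MHC class I (16 tested, 0.143), inhibitory markers (15 tested, 0.926), microglia (13 tested, 0.671) and fibroblast markers (20 tested, 0.802). Cell-cycle inhibitors (18 tested, 2 higher and 1 lower when adjusted over the list alone) did not pass (camera adjusted p = 0.983). For cell-cycle inhibitors and inhibitory markers the median and mean were above 0 and the test pointed down. For interferon the median alone was above 0, and for fibroblast markers the mean alone. Without etoposide library 1 the calls of NRF2 targets (camera adjusted p = 0.0596), lysosome (0.289) and pan-neuronal markers (0.281) were lost, as were that of lysosome without DMSO library 1 (0.0657) and that of oxidative phosphorylation without DMSO library 3 (0.734). Without etoposide library 2, complement (0.0360), MHC class I (0.0274), microglia (0.0469) and fibroblast markers (0.0234) passed upward. Without DMSO library 2, complement (0.0400) and microglia (0.000294) did. By camera 8 lists passed upward and 9 downward of 25, but 5 of the 10 splits of these 6 libraries gave at least as many passing lists.

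The last comparison asked what the 2 models share. Of 12179 genes tested in both, 0 were called in the same direction, with 56 etoposide calls, and limma made 0 higher etoposide calls that could have matched. On simulated data this etoposide fit called 1% of genes changed 2-fold and 52% of those changed 4-fold. The 0 therefore does not show that the models share no gene. Hmga1b and Fas, which rose with H-Ras(G12V), read 412, 207 and 0.22 and 13.4, 7.92 and 5.81 FPKM in etoposide libraries 1, 2 and 3. In DMSO they read 0.0800 ± 0.0361 and 2.20 ± 0.370 FPKM (limma adjusted p = 0.353 and 0.127). 43 genes were called higher with H-Ras(G12V) and lower with etoposide, where independent lists would give 5.34. Among them Gpr17 had log2 fold changes of 2.19 ± 0.58 and -4.50 ± 0.29 (SE), Sox10 of 1.67 ± 0.37 and -4.47 ± 0.27, and Ube2c of 1.09 ± 0.18 and -3.72 ± 0.30. Lhfpl3 and C1ql1, which are expressed in oligodendrocyte precursors, had differences between the effects of 5.02 ± 0.67 and 5.01 ± 0.54 (interaction adjusted p = 0.00112 and 0.000301). The etoposide call of Lhfpl3 was lost without etoposide library 2 (limma adjusted p = 0.176) or DMSO library 1, 2 or 3 (0.0846, 0.0807 and 0.0587). It was also lost with no filter (0.101), scaling to a common sum (0.0647) or a replicate block (0.103). That of C1ql1 was lost without etoposide library 2 (0.0508) or DMSO library 3 (0.0587). The H-Ras(G12V) call of Gpr17 lay at 0.0452, with mCherry libraries at 4.24, 3.57 and 20.8 FPKM. For these genes too, a change in the mixture of cells cannot be told apart from a change within neurons.

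Across genes, log2 fold changes of the models correlated at Pearson r = 0.172 and Spearman rho = 0.172, and genes are not independent replicates. The interaction contrast called 339 genes, 305 with the higher effect in H-Ras(G12V) and 34 with the higher effect in etoposide, and 2109 at an unadjusted p under 0.05. For C4b the effects differed by 1.55 ± 0.51 (adjusted p = 0.147) and for Cdkn1a by -0.05 ± 0.60 (adjusted p = 0.975). The shared count rested on etoposide library 3. Without etoposide library 3, 398 genes were higher in both and 281 lower in both, where independent lists would give 207 and 112. A further 184 were higher with H-Ras(G12V) and lower with etoposide and 29 the opposite, where 156 and 149 would be given. The interaction then called 2587 genes.

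**Figure D3:**
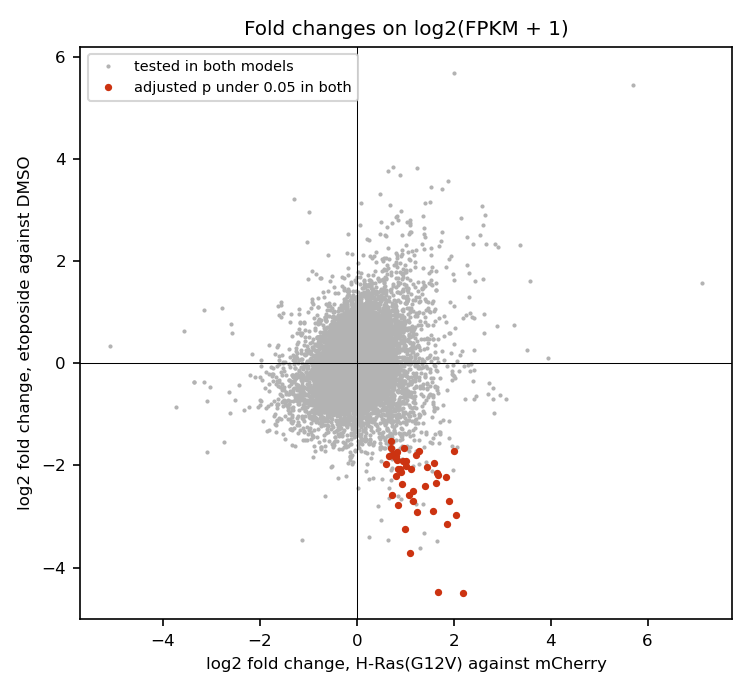
Log2 fold change of each of 12179 genes with H-Ras(G12V) against mCherry (x axis) and with etoposide against DMSO (y axis), both on log2(FPKM + 1). Red points are the 43 genes that passed in both tests, and each lies above 0 on the x axis and below 0 on the y axis.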

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

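The weighing tests of the libraries that stand apart and of the conflicting labels were chosen after the results were seen. The counts of splits and the interaction test were planned.

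The effects of the 2 models were tested against each other, and 339 genes differed. Among named genes, the H-Ras(G12V) log2 fold change exceeded that of etoposide for members of the oligodendrocyte lineage list, by 6.69 for Gpr17, 6.14 for Sox10, 4.91 for Pdgfra, 4.05 for Olig2, 3.70 for Cldn11 and 3.26 for Cspg4. It did so for members of the DNA replication and mitosis list, by 4.80 for Ube2c, 4.22 for Ccnb1, 3.67 for Mcm5, 3.65 for Cdc20 and 3.63 for Ccna2. For genes on the astrocyte and progenitor lists the excess was 3.22 for Hes5, 3.10 for Aldh1l1, 2.32 for Ntsr2 and 1.96 for Fgfr3. It was 5.56 for Gal, 5.12 for Bcas1, 5.02 for Lhfpl3, 5.01 for C1ql1, 3.65 for Rlbp1, 3.30 for Nptx2, 3.24 for Cdkn2a and 2.33 for Lmnb1. The interaction was tested per gene, not per list. The difference ran the other way for Igf2 (-5.42), Vtn (-3.01) and Calb2 (-2.34). Interaction adjusted p was 0.0210 for Cldn11, the highest of these genes. Several of these genes mark cell types other than neurons, so a different mixture of cells cannot be told apart from a change within neurons.

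Among the 100 pairs of splits of the libraries, 3 gave as many interaction calls as the real grouping, the real pair included, a share under 0.05. The highest other pair gave 3000, several times the real 339, which points to a structure of the libraries other than the groups. What that structure is was not tested, and with it the share does not exclude chance. The splits also shuffle groups within each table, so an effect in 1 model alone could rank the real pair high. For the correlation of 0.172, 61 of 100 pairs gave an absolute value as large, the highest being 0.518, so chance cannot be excluded. Each split other than the real one called 0 genes in its table, so every other pair could only give 0 genes called in both. The 43 genes called in opposite directions, as large in 1 of 100 pairs, and the 0 shared in direction, as large in 100 of 100 with 0 as the highest other, therefore say nothing about chance. With 6 libraries per table, the 10 splits are too few for a share under 0.05. The real splits gave 2161 and 56 genes, with 1 split of 10 as large in each and 0 genes as the highest other. The real H-Ras(G12V) split gave 20 passing lists against 15 as the highest other, with 1 split as large. The real etoposide split gave 17 against 20, with 5 splits as large.

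Etoposide library 3 stood apart from libraries 1 and 2. A DMSO culture of this series under a wrong label is argued against by the DNA replication and mitosis list, whose median lay 1.82 log2 units below the DMSO mean (-1.82), while the DMSO libraries spanned -0.26 to 0.25. A difference in depth as the whole cause is argued against by genes at 20 FPKM or more in each library of a group, of which 11.2% lay at least 2-fold from both other etoposide libraries in library 3, and at most 2.33% in a DMSO library from the other DMSO libraries. A smaller response to etoposide stays open, since the lists part: its p53 target median of 0.437 lay below those of libraries 1 and 2 (1.54 and 1.44) and above the DMSO libraries (at most 0.10), while its DNA replication and mitosis median lay below theirs (-1.47 and -1.34). A different culture, dose or time of collection may also have produced it, and the labels give no batch with which to test this.

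mCherry library 3 stood apart from libraries 1 and 2. An H-Ras(G12V) culture under a wrong label is argued against by its RAS-ERK median of 0.427, where the libraries labelled H-Ras(G12V) lay between 1.06 and 1.39. A few genes taking a larger share is argued against by the 10 highest genes, which held 4.87% of its summed FPKM against 5.52% and 5.51%. A different mixture of cell types may account for it, since 3 cell type lists differed by over 1 log2 unit from the mean of libraries 1 and 2, namely astrocyte (1.04), oligodendrocyte lineage (1.27) and microglia (-2.18) markers. The shift was not confined to cell type lists. Relative to the mCherry mean, the immediate early list had a median of 1.38 in library 3 and of -0.48 and -0.66 in libraries 1 and 2. What moved that list was not tested. No biological explanation other than that mixture was tested, as the design gives none within a group.

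The labels disagree on which libraries had etoposide. That the titles name the groups the wrong way round is argued against by the DNA replication and mitosis list, which lay below the DMSO mean in each library titled etoposide, at -1.34 in the highest of them. The p53 target list was above the DMSO mean in the same libraries, at 0.437 in the lowest.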

How the results depend on the processing

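Averaging mCherry libraries 1 and 2 and leaving out the third mCherry library together with the third etoposide library were chosen after seeing the data, and the other alternatives were planned. Weights per library were also tried after seeing the data, did not converge and were not used. The value followed for a gene list is its mean log2 fold change, which replaced the median after the first output was seen. Over 739 list values under alternatives the mean changed sign in 19, the median in 33 and the direction of the test in 21.

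The 2161 H-Ras(G12V) calls stayed within 1.5 times under other pseudocounts, filters and scalings and with robust eBayes. They were 307 with all 12 libraries in 1 fit, 630 with mCherry libraries 1 and 2 averaged, and 507 to 5722 with 1 library left out, the highest without mCherry library 3. The 56 etoposide calls were 22 with a mean of at least 5 FPKM, where fewer genes are tested, 175 in the single fit and 4 to 3908 with 1 library left out. Genes shared in direction were 4 in the single fit, 0 to 679 with 1 library left out, and 1394 without the third mCherry and the third etoposide library. Genes called in opposite directions were 16 with a mean of at least 5 FPKM, 15 with mCherry libraries averaged, 2 to 213 with 1 library left out, and 611 without the third mCherry and the third etoposide library. Interaction calls were 599 with no filter, 161 with a mean of at least 5 FPKM, 189 with mCherry libraries averaged, 183 to 2587 with 1 library left out, and 3663 without the third mCherry and the third etoposide library. The correlation of log2 fold changes ranged from -0.0075, without etoposide library 1, to 0.266, without etoposide library 3. Fewer libraries or genes are part of these alternatives. The single fit keeps the log2 fold changes and pools the spread of all 4 groups. In the separate fits the median SE was 0.164 for H-Ras(G12V) and 0.318 for etoposide. Otherwise the cause was not tested.

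With a replicate block the H-Ras(G12V) calls were 1681, the etoposide calls 12 and the opposite calls 9. With H-Ras(G12V), Gdf15 passed (adjusted p = 0.0172), the complement, immediate early and microglial lists passed upward (camera adjusted p = 0.0304, 0.0156 and 0.000338), and NRF2 targets did not pass (0.0553). With etoposide, the oligodendrocyte list did not pass with an estimated correlation (adjusted p = 0.621). Same-numbered libraries did not deviate together, with correlations of -0.04, 0.03 and 0.12 in the H-Ras(G12V) table and -0.26, -0.17 and -0.15 in the etoposide table, so the numbers were not taken to pair the libraries.

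Apart from oxidative phosphorylation with etoposide, the gene and list values that changed sign had not passed a test. The correlation also changed sign, and for it chance was not excluded. Inhibitory markers with etoposide had a mean of -0.0147 with a pseudocount of 0.1, -0.0874 scaled to a common sum, -0.0631 with median-of-ratios scaling, and -0.207 to 0.291 with 1 library left out. With H-Ras(G12V), endothelial markers had a mean of 0.0227 with a pseudocount of 5, cholesterol biosynthesis -0.0416 scaled to a common sum and -0.0237 to 0.160 with 1 library left out, and Hras -0.300 to 0.0059. With etoposide and 1 library left out, ranges were -0.0142 to 0.629 for Cdkn2a, -0.0852 to 0.256 for Glb1, -0.0624 to 0.554 for complement, -0.0367 to 0.432 for cell-cycle inhibitors, -0.152 to 0.999 for microglia, -0.219 to 0.604 for fibroblast markers, -0.137 to 0.0972 for interferon, -0.428 to 0.103 for progenitor markers and -0.266 to 0.0050 for oxidative phosphorylation. The cause was not tested. Of 1538 values of genes that the naming rule took for H-Ras(G12V), 1183 kept their direction and side of the threshold, 349 lost the call, 5 gained it and 1 changed sign. Of 371 for etoposide, 319 kept them, 41 lost the call, 9 gained it and 2 changed sign. Depth limits low genes most.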

Other observations

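Some list members not yet given moved with H-Ras(G12V). Gpnmb, a lysosomal membrane glycoprotein, rose from 10.4 ± 4.12 to 52.4 ± 15.2 FPKM (SD, n = 3 per group; limma adjusted p = 0.00590). Among MHC class I genes, H2-D1 rose from 28.6 ± 8.92 to 56.0 ± 8.99 FPKM (adjusted p = 0.0400) and H2-K1 from 29.2 ± 5.20 to 45.1 ± 2.50 FPKM (adjusted p = 0.0335). Isg15, an interferon-induced gene, fell from 3.39 ± 1.00 to 1.07 ± 0.370 FPKM (adjusted p = 0.0213). Among interneuron markers Calb2, which encodes calretinin, fell from 84.3 ± 23.8 to 17.6 ± 0.400 FPKM (adjusted p = 0.00267).

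The test of gene length was planned as a hypothesis before its result was seen. Topoisomerase poisons can slow transcription through long genes, so etoposide may lower long genes more than short ones. Across 12165 genes with a span in the reference annotation (98.3% of those tested), Spearman's rho between the log2 difference from the DMSO mean and gene span was -0.15, -0.05 and 0.296 in etoposide libraries 1, 2 and 3. The H-Ras(G12V) libraries, set against the mCherry mean over 12510 genes, gave -0.11, -0.26 and -0.12. A negative rho was thus not particular to etoposide. Single DMSO libraries against the mean of the other DMSO libraries gave 0.45, 0.34 and -0.47, a wider range than the etoposide libraries. These values are not independent, since each DMSO library is in the baseline of the others and in the DMSO mean used for etoposide. The median log2 difference of genes over 100 kb was -0.448 in DMSO library 3, against 0.201 and 0.244 in libraries 1 and 2. The hypothesis therefore cannot be told apart from the spread between control libraries, which keeps it open. Genes are not independent replicates here.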
